A study of Triticum aestivum and unidentified soil bacteria with 9 samples.

How the data were processed

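Genomic DNA of the bacterial community was taken from the root endosphere, the interior of the root, of wheat grown in a randomized complete block field trial, and from soil. Per the labels, plots of 5 m2 were laid out in 3 replications, and inoculation was by coating seeds with a mix of broth culture and 10% sugar solution. This text is the same for all groups, so the coating of control seeds, if any, is not known. The labels do not say which library came from which plot, so p-values measure the spread between these libraries, which may be partly technical.

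The authors deposited whole-number counts of sequences per OTU, with 1 column for each of 9 libraries. All 9 columns sum to 37589, which means that the deposited counts had been subsampled to 1 depth before deposit, as found from the values. The depth before subsampling, the amplified region, the clustering tool, the reference database and any filters are not given in the sources used here. The table holds 630 OTUs, of which 142 have 1 count in total, and 1 further line that gives the number of OTUs and was left out. It pairs no OTU with a taxon. Planned results on the family of the inoculated strain, on phyla, on lists of taxa and on plant organelle sequences could therefore not be computed, and any organelle sequences among the OTUs stayed in. A table of wheat genes was not used here.

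Columns were assigned to groups by their names. The names carry the letters A, B and C, which the labels do not tie to the replicate numbers of the titles, so libraries are named by letter and were not paired. The control columns are coded C-F-Rt where the titles read C-S-Rt. They were taken as control roots because these are the only titles with the control and root codes. Within each group, the counts of every pair of libraries differed far beyond sampling noise, with chi-square values between 43.4 and 378 times their degrees of freedom, so no pair looked like 1 library deposited under separate names. Read-sampling noise leaves out the noise of PCR, so this does not show that the libraries came from separate plants or plots.

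Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 on all 9 libraries, with 1 coefficient per group. Low OTUs were removed by filterByExpr with a minimum count of 10, which left 70 OTUs holding 91.4 to 99.3% of each library. Libraries were scaled by TMM on these OTUs, with factors of 0.303 to 0.430 in soil, 1.09 to 1.37 in control roots and 1.91 to 2.86 in SA187 roots. The contrasts were SA187 against control roots, and the mean of both root groups against soil. OTUs with a Benjamini-Hochberg adjusted p under 0.05 were called. The SE of a log2 fold was back-calculated as its absolute value over the square root of the test's F statistic. It is thus an approximation and not an error that the fit itself gave. Shares are percent of the 37589 counts computed from the deposited counts, and the percent intervals of single libraries are Wilson 95% intervals. A fold against a group at 0 was computed as a lower bound, against 3 counts over the group's 3 libraries.

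Richness is the number of OTUs with a count above 0, and needed no rarefaction at equal totals. The Shannon index used natural logarithms. Group differences in both were tested by exact two-sided permutation of the difference of means for each pair of groups (10 splits) and of the F statistic over 3 groups (280 groupings). Composition was tested by PERMANOVA on Bray-Curtis dissimilarities of shares over the same groupings, with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 in Python 3.11.15. Figures were drawn with matplotlib 3.10.9.

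The steps were tested on simulated data with known answers. Over 50 simulations of each comparison, 20 OTUs were changed, 10 by 4-fold and 10 by 16-fold, never Otu001, Otu002 or Otu003. Counts were drawn with the spread estimated from the data. For SA187 against control roots, both root groups started from their pooled mean and soil from its own. For roots against soil, all libraries started from the same mean. The real imbalance between the groups compared was thus not simulated in either case, and the rates need not hold for the real counts. For SA187 against control roots edgeR found 3.6% of the 4-fold and 27.8% of the 16-fold changes with a mean of 0.32 false calls among 83.7 tested OTUs. For roots against soil it found 9.8% and 52.4% with 0.36 false calls among 85.1 tested OTUs.

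Groups, tests, the OTUs to be named and most alternatives were fixed before the data were examined. Named were OTUs past the test whose libraries did not overlap, by size of fold, or the 10 of smallest p where fewer than 5 passed, and the 8 OTUs of highest mean share in each group. As the IDs carry no taxon, at most 2 called OTUs per direction are given with full statistics, and Otu008 was taken among them for its abundance. The settings compared with these were DESeq2 1.42.0 with poscounts size factors, TMMwsp factors, library totals alone, no filter, a stricter filter, limma 3.58.1 on centred log ratios with zeros set to 0.5 counts, fits on fewer groups, other indices and distances, and each library left out in turn. Leaving out Otu001 or the 3 most abundant OTUs, testing both root groups together against soil on richness, Shannon index and composition (84 splits), and counting non-overlapping OTUs under each scaling were chosen after seeing the data.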

Results

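Sequences from the bacterial communities inside wheat roots and in soil were counted per operational taxonomic unit (OTU), a cluster of similar sequences that stands in for a bacterial taxon. The plants were durum wheat of the local variety Karim, although the organism field of the labels names Triticum aestivum. They grew under desert farming in plots of 5 m2 with a soil pH of 7.45 and a soil salinity of 1.9 dS/m, irrigated with water of 0.3 dS/m. The inoculum, coated on the seeds as broth culture in sugar solution, was Enterobacter sp. SA187, an endophyte from a desert plant that has been studied for raising the stress tolerance of crops. Control plants had no agent per the labels, which do not say whether their seeds were coated with sugar solution or broth without the strain. Each of the 3 groups (control roots, SA187 roots and soil) had 3 libraries, called A, B and C below. Every library held 37589 counts spread over a table of 630 OTUs, so the libraries did not differ in depth as deposited. A count of 0 in a library allowed a share of up to 0.00798% of its reads, and this floor, like all intervals given for single libraries, covers counting error only. The 3 control columns carry a middle letter that differs from the one in the control titles, and they were assigned to the control roots because no other titles combine the control and root codes. All control values rest on that reading. The letter is F in all root columns and in the SA187 titles and S in the control titles, while soil names begin with S. The labels do not say what F and S mark, and give the same soil and irrigation values for all groups. Any condition they mark would follow inoculation by the titles, or roots against soil by the columns, and could not be told apart from it. The table used here pairs no OTU with a taxon, so OTUs are given by ID, and the share of the inoculated strain or its family was not analysed here.

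The first question was whether inoculation with SA187 went with a different community inside the root. SA187 roots held more OTUs than control roots, with 250.3 ± 13.8 (SD, n = 3) detected per library against 181.0 ± 17.3 (n = 3). All 3 SA187 libraries, at 240 to 266 OTUs, lay above all 3 control libraries, at 162 to 196. Their reads were also spread more evenly: the Shannon index was 2.80 ± 0.24 in SA187 roots and 2.25 ± 0.20 in control roots (SD, n = 3 each). The most abundant OTU of a library took 22.8 ± 2.61% of the reads in SA187 roots and 41.3 ± 8.64% in control roots (SD, n = 3 each). The difference in richness was 69.3 OTUs and the difference in Shannon index was 0.548, each with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 can give. Neither difference could therefore pass a threshold of 0.05. OTUs of at least 1% of a library numbered 13.3 ± 1.15 in SA187 roots and 10.7 ± 1.15 in control roots (SD, n = 3 each).

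**Figure D1:**
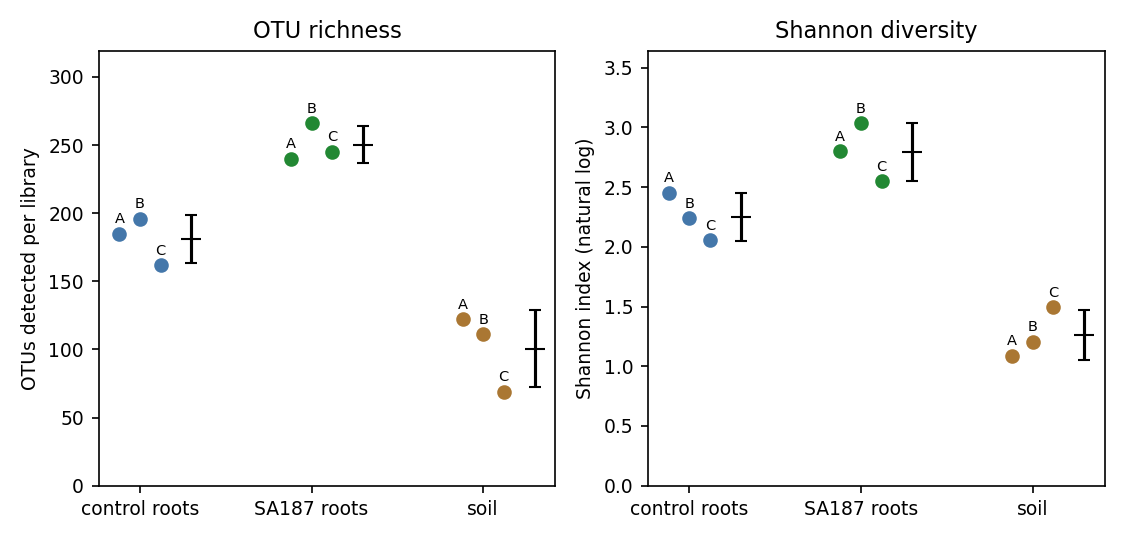
OTUs detected per library (left) and Shannon index with natural logarithm (right) in control roots, SA187 roots and soil. Each lettered point is 1 library, the bar beside it is the mean with its SD (n = 3), and SA187 libraries sit at 240 to 266 OTUs, control libraries at 162 to 196 and soil libraries at 69 to 122.

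Control roots held 312 OTUs over their 3 libraries and SA187 roots held 432, of which 228 were seen in both groups. The 204 OTUs seen in SA187 roots and not in control roots took 2.18 ± 1.92% of the SA187 reads (SD, n = 3), and 1.09 ± 0.401% without library A (SD, n = 2). In that library 1182 such counts came from Otu019, an OTU singled out after its values were seen. The 84 OTUs seen in control roots and not in SA187 roots took 0.465 ± 0.294% of the control reads (SD, n = 3). Most root reads thus came from OTUs that both root groups held. Bray-Curtis dissimilarity, which runs from 0 for identical communities to 1 for communities with no shared OTU, averaged 0.408 between control and SA187 libraries. It averaged 0.474 within the control group and 0.319 within the SA187 group. The split by treatment gave a share R2 of 0.219 of the variation in composition among the 6 root libraries. Its exact permutation p was 0.4, where 0.1 is the smallest possible, so some other splits gave an R2 at least as large. That smallest p was reached with Jaccard dissimilarity on presence and absence (R2 = 0.241), with square-root shares (R2 = 0.258) and with Bray-Curtis without control library A (R2 = 0.361), so the p-value depends on the distance and on that library. Aitchison distance gave an R2 of 0.214 with an exact permutation p of 0.3, and leaving out each of the other root libraries gave p between 0.4 and 0.9.

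The same OTUs led both root groups, at shares that varied widely between libraries. Otu002 took 26.7 ± 22.0% of the reads in control roots, with single libraries between 8.64% and 51.3%, and 18.5 ± 7.51% in SA187 roots (SD, n = 3 each). Otu004 stood at 19.8 ± 14.9% in control roots and 10.9 ± 8.37% in SA187 roots. Otu005 stood at 16.2 ± 16.9% in control roots and 9.67 ± 4.30% in SA187 roots. Otu003 had a share of 9.72 ± 1.56% in control roots and 19.2 ± 3.91% in SA187 roots, with no overlap between the libraries. The share of Otu008 was 2.85 ± 1.52% and 6.40 ± 2.16%, and that of Otu011 was 0.693 ± 0.188% and 4.02 ± 3.26%, again without overlap. Otu009 had nearly equal mean shares of 4.15 ± 1.23% in control roots and 4.22 ± 0.575% in SA187 roots. The Wilson 95% interval of any such share in a single library was at most 1.01 percentage points wide.

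**Figure D2:**
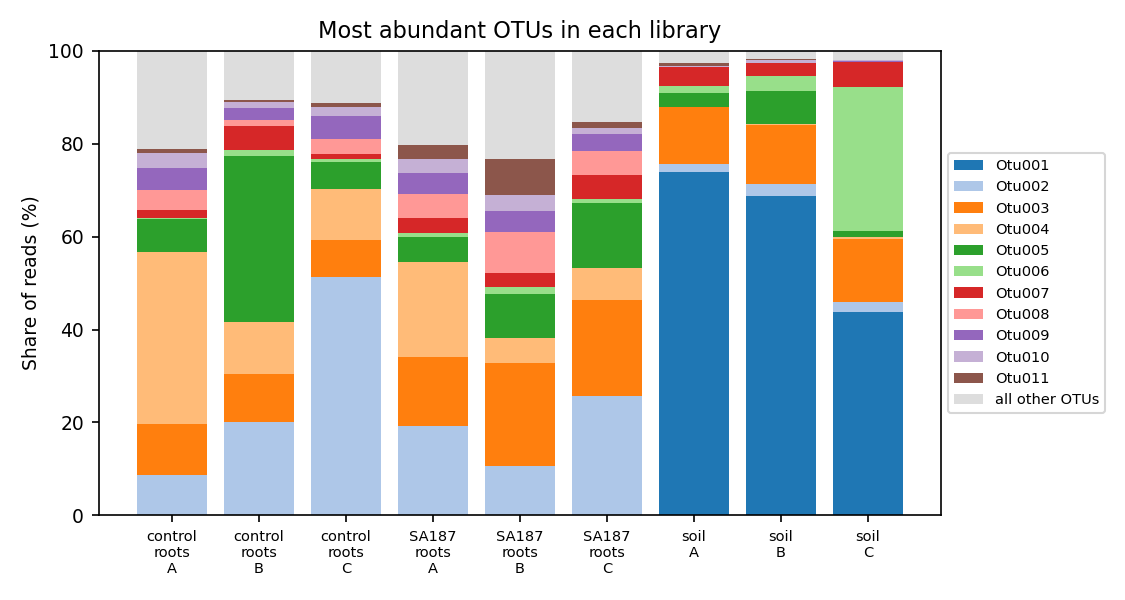
Share of reads (%) of the 11 OTUs that were among the 8 most abundant of any group, stacked for each of the 9 libraries, with all other OTUs in grey. Otu001 takes 43.7 to 74.0% of the soil libraries and is nearly missing from the roots, where Otu002, Otu003, Otu004 and Otu005 have the highest mean shares.

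No OTU passed the test between SA187 and control roots. Of 70 OTUs tested with edgeR's quasi-likelihood test on TMM-scaled counts, 0 had a Benjamini-Hochberg adjusted p under 0.05, while 5 had an unadjusted p under 0.05. DESeq2 called 1 OTU and limma on centred log ratios called 1, in both cases Otu029, which was higher in SA187 roots. Otu029 had the smallest p in edgeR's test as well, with a log2 fold of 3.42 (SE 0.98) and an edgeR adjusted p of 0.253. Its share was 0.389 ± 0.287% in SA187 roots and 0.0160 ± 0.0141% in control roots (SD, n = 3 each), with all 3 SA187 libraries above all 3 control libraries. In the opposite direction, Otu001 had the smallest p, with an edgeR adjusted p of 0.253. It had only 6 counts in control roots and 0 in SA187 roots, so its fold has no finite estimate and is not given. Otu034 came next, with a log2 fold of -4.02 (SE 1.51) and an edgeR adjusted p of 0.431. The libraries of both OTUs overlapped. On simulated counts for this comparison the test found 27.8% of OTUs changed 16-fold and 3.6% of those changed 4-fold. At these rates changes of that size in single OTUs would mostly have been missed. The simulation started both root groups from the same mean and never changed Otu001, Otu002 or Otu003, so the rates need not hold for the real counts.

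How the libraries were scaled decided the direction of many small differences. As plain shares of reads, 20 of the 70 tested OTUs had all 3 SA187 libraries above all 3 control libraries and 0 had them all below, where chance gives 10% of OTUs, or 7. After TMM scaling, 6 OTUs were wholly higher and 4 wholly lower, against 10 and 1 with TMMwsp factors and 7 and 3 with centred log ratios. Replacing TMM by the library totals moved the median log2 fold by 0.99, and the log2 fold of Otu003 went from -0.01 to 0.98 with it.

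The second question was how the communities inside the roots differed from that of the soil. Soil was the least diverse of the 3 groups, with 100.7 ± 28.0 OTUs per library and a Shannon index of 1.26 ± 0.209 (SD, n = 3). A single OTU, Otu001, took 62.1 ± 16.2% of the soil reads (SD, n = 3). Its taxon was not analysed here and a mix-up of samples or a reagent sequence was not ruled out, so values for soil are those of the libraries labelled soil. In the roots Otu001 was almost missing, with 6 of 225534 counts, all of them in control roots. In SA187 roots it had 0 of 112767 counts, which allows a share of up to 0.00266%. The 8 most abundant OTUs of each group together took 97.6 ± 0.441% of the soil reads, 84.2 ± 5.47% of the control root reads and 76.8 ± 5.44% of the SA187 root reads (SD, n = 3 each).

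Richness and Shannon index differed among the 3 groups, with an exact permutation p of 0.00357 for each, the smallest that 280 groupings of 9 libraries can give (F = 39.6 and F = 38.3). Control roots held 80.3 more OTUs than soil and SA187 roots 149.7 more, each with an exact permutation p of 0.1, the smallest possible. Both root groups together exceeded soil by 115.0 OTUs and by 1.26 in Shannon index, each with an exact permutation p of 0.0119, the smallest that 84 splits can give. Groups accounted for an R2 of 0.731 of the Bray-Curtis variation among all 9 libraries, with an exact permutation p of 0.0143. Mean dissimilarity was 0.797 between control roots and soil and 0.751 between SA187 roots and soil. Within soil it was 0.250, although soil libraries A and B differed by only 0.0837. With Otu001 left out and all libraries brought to 9776 counts, the difference between roots and soil was 51.0 OTUs, with an exact permutation p of 0.0357. It was 29.1 for control roots, whose libraries then overlapped with soil (exact permutation p = 0.2), and 73.0 for SA187 roots (exact permutation p = 0.1, the smallest possible).

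Of 516 OTUs seen in roots and 193 seen in soil, 79 were seen in both. These 79 OTUs held 94.7 ± 2.89% of the root reads (SD, n = 6) and 99.4 ± 0.0865% of the soil reads (SD, n = 3), at shares that differed between roots and soil. The soil value counts Otu001 as seen in roots on 6 counts, and the other shared OTUs held 37.2 ± 16.2% of all soil reads, or 98.1 ± 0.901% of the soil reads that were not Otu001 (SD, n = 3 each).

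Root and soil communities also differed OTU by OTU. Among the 70 OTUs tested with edgeR's quasi-likelihood test, 34 passed at a Benjamini-Hochberg adjusted p under 0.05, with 25 higher and 9 lower in roots. The 25 higher OTUs together held a mean of 29.2% of the root reads and 0.369% of the soil reads. The largest part of that root share was Otu004, with 19.8 ± 14.9% in control roots and 10.9 ± 8.37% in SA187 roots (SD, n = 3 each). Of these 25, 15 had no count in any soil library and 23 had all 6 root libraries above all 3 soil libraries. Among all 70 tested OTUs, called or not, 35 had their root libraries above soil in this way. Otu008 was higher in roots with a log2 fold of 5.58 (SE 0.96, edgeR adjusted p = 0.00416), from a soil share of 0.0186 ± 0.0138% (SD, n = 3). Otu028 had no count in soil and was higher in roots (edgeR adjusted p = 0.00688), by at least 80.2-fold on shares and at least 19.4-fold after TMM scaling, measured against a floor of 3 counts over the soil group. Its share was 0.274 ± 0.186% in control roots and 0.153 ± 0.0603% in SA187 roots (SD, n = 3 each).

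The 9 lower OTUs held a mean of 18.9% of the root reads, 14.5% of the root reads being Otu003, and 91.6% of the soil reads. Of these 9, 3 had all 6 root libraries below all 3 soil libraries. Otu001 was lower in roots (edgeR adjusted p = 2.25e-05 for both root groups against soil). In control roots its log2 fold against soil was -15.31 (SE 1.83, edgeR adjusted p = 0.000349), and in SA187 roots, where it had no count, its share was at least 23359-fold lower than in soil against a floor of 3 counts over the group. Its share in soil libraries A, B and C was 74.0% (Wilson 95% interval 73.5 to 74.4%), 68.7% (68.2 to 69.2%) and 43.7% (43.2 to 44.2%). Otu006 was lower in roots with a log2 fold of -6.15 (SE 1.09, edgeR adjusted p = 0.00416). Its soil share of 11.9 ± 16.4% (SD, n = 3) came mostly from library C, where it took 30.8% (Wilson 95% interval 30.3 to 31.3%), and without that library the log2 fold was -4.24. Root shares of Otu006 were 0.746 ± 0.639% in control roots and 1.03 ± 0.399% in SA187 roots. Among the OTUs that led the roots, Otu004 stood at 0.232 ± 0.228% in soil and Otu009 at 0.0913 ± 0.0984% (SD, n = 3 each). Both were called higher in roots (edgeR adjusted p = 0.0182 and 0.0165). Otu002 stood at 2.11 ± 0.448% in soil and Otu005 at 3.79 ± 2.96%, and neither passed edgeR's test between roots and soil (adjusted p = 0.146 and 0.647). All 6 root libraries lay above all 3 soil libraries in their share of Otu002, which passed with library totals in place of TMM (log2 fold 3.40, edgeR adjusted p = 0.00239). Otu007 stood at 4.03 ± 1.34% in soil, 2.68 ± 2.19% in control roots and 3.82 ± 1.17% in SA187 roots. It was among the 9 lower OTUs under TMM (log2 fold -2.53, edgeR adjusted p = 0.0105), but its libraries overlapped and library totals gave -0.33 (edgeR adjusted p = 0.616). Otu010 stood at 0.435 ± 0.281% in soil, 2.18 ± 1.11% in control roots and 2.57 ± 1.08% in SA187 roots, with all root libraries above soil. It did not pass under TMM (log2 fold 0.26, edgeR adjusted p = 0.719) and passed with library totals (log2 fold 2.45, edgeR adjusted p = 0.0167).

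The folds between roots and soil depend on the scaling, as library totals in place of TMM moved their median by 1.99 on the log2 scale. With library totals 53 OTUs passed, 51 higher and 2 lower in roots. Of these, 27 were also among the 34, 25 of them higher and 2 lower. Otu003 changed direction, with a log2 fold of -2.13 under TMM and 0.091 under library totals, and its soil share of 12.8 ± 0.681% (SD, n = 3) lay between those of the root groups. Without soil library A, 19 OTUs passed, 9 higher and 10 lower, and the number higher was 14 without soil library B and 16 without SA187 library B. Control roots alone against soil gave 17 OTUs and SA187 roots alone gave 24, and the difference between these counts was not tested.

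**Figure D3:**
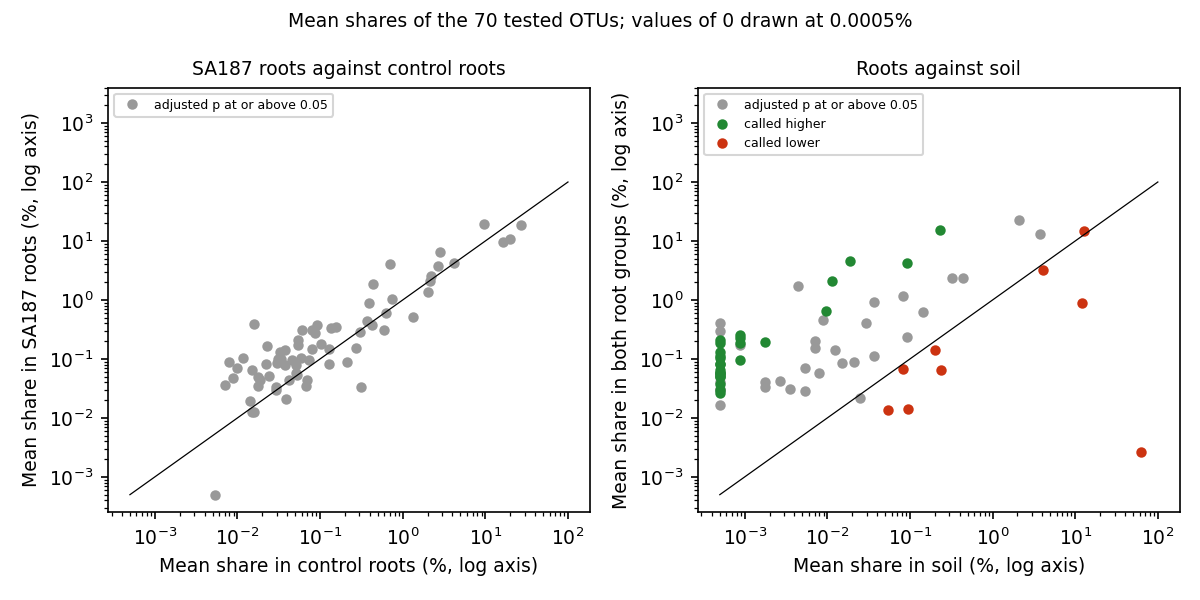
Mean share of reads of each of the 70 tested OTUs on logarithmic axes (%), SA187 against control roots on the left and the mean of both root groups against soil on the right, with values of 0 drawn at 0.0005% and the line marking equal shares. On the left 0 OTUs passed edgeR's test; on the right 25 OTUs called higher in roots and 9 called lower are coloured, and 1 of the 9, Otu003, lies above the line because its direction differs between shares and TMM-scaled counts.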

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

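No paired analysis was possible because the columns carry letters that the labels tie neither to replicate numbers nor to field blocks, so the planned replicate block was not run. Also not run were the settings on organelle sequences, on a pseudocount for normalized values and on depth (all totals are equal), and all results on Enterobacteriaceae, phyla and taxon lists, since the table pairs no OTU with a taxon.

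Between SA187 and control roots the count of called OTUs was 0 in edgeR, 1 with DESeq2, 1 with limma on centred log ratios and 2 with no filter, and it stayed at 0 in each of the other settings and without each library in turn (0 to 0). Adjusted p for Otu029 ranged from 0.0344 (DESeq2) to 0.724 over its 17 alternatives. The 2 OTUs called with no filter, chosen for mention after their values were seen, were Otu019 (1182 counts, all in 1 SA187 library) and Otu050 (183 counts, all in 1 control library). The difference in richness reversed to -1.33 OTUs (exact permutation p = 0.3) when only the 35 OTUs with a mean share of at least 0.1% were counted, a count near its ceiling in both groups (30.7 and 32.0). R2 of Bray-Curtis between SA187 and control roots ranged from 0.158 (without SA187 library B) to 0.361 (without control library A), and it was 0.241 with Jaccard and 0.258 with square-root shares, each at an exact permutation p of 0.1, the smallest possible.

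Between roots and soil the 34 calls became 53 with library totals, 15 with the stricter filter, which tested only 34 OTUs, and 17 with control roots alone. DESeq2 gave 33 calls (22 higher, 11 lower), TMMwsp 43 (34 and 9), no filter 29 (15 and 14) and centred log ratios 24 (14 and 10). With Otu001 or the 3 most abundant OTUs left out, 33 passed in each case. Leaving out 1 library gave 19 to 35 calls, and the 25 higher calls became 9 without soil library A, 14 without soil library B and 16 without SA187 library B. Otu003 reversed to a log2 fold of 0.091 with library totals, a move of the same kind as the median shift of 1.99 that this scaling gave over the tested OTUs.

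Of the alternatives to the permutation tests, 74 could reach p under 0.05 and did so, at most 0.0357, while 111 were too small to reach it and say nothing about stability. Among named OTUs called between roots and soil, 286 of 365 alternatives kept call and direction, 78 lost the call and 1 reversed. Named OTUs that were not called changed sign in 21 alternatives between SA187 and control roots and in 20 between roots and soil, and 5 alternatives gained a call (2 and 3). The equal depth of 37589 counts limits what can be said of OTUs under about 0.00798% of a library.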

Other observations

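Root OTUs were set in classes by mean share over all 6 root libraries, a choice made after the data were seen, and the difference between classes was not tested. The mean was higher in SA187 roots for 7 of 12 OTUs of at least 1%, 17 of 28 between 0.1 and 1%, 75 of 102 between 0.01 and 0.1%, and 238 of 374 below that. The 12 OTUs of at least 1% took 89.5 ± 0.544% of the reads in control roots and 84.7 ± 4.70% in SA187 roots (SD, n = 3 each, exact permutation p = 0.4). The 102 OTUs between 0.01 and 0.1% took 2.16 ± 0.303% and 4.42 ± 1.68% (exact permutation p = 0.1, the smallest possible). Among the 374 OTUs under 0.01%, a control library held 80.7 ± 11.1 and an SA187 library 139.3 ± 11.1 (SD, n = 3 each). Shares in a library sum to 100%, so these classes are not independent of each other. In 4 cases an OTU had at least 50 counts in 1 library and 0 in the other 8, 2 of them in control roots and 2 in SA187 roots.

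The patterns weighed next were noticed in the data, and the bound that would decide each test was written down before its result was seen, apart from the count of non-overlapping OTUs, which was chosen afterwards. The count of 0 called OTUs between SA187 and control roots was met by all 10 of the 10 splits of the 6 root libraries, with 1 call in the highest other split. Every split meets a count of 0 by construction, and 10 splits are too few to give a share under 0.05, so this decides nothing. Counted as shares, 20 tested OTUs did not overlap in the real split and 9 in the highest of the other 9 splits, but after TMM scaling both numbers were 10. A fit with only 2 groups, roots and soil, called 41 OTUs in the real split and 1 in the highest of the other splits. Only 1 of 84 splits gave as many, a share of 0.0119, the smallest that 84 splits can give. Every other split mixes root and soil libraries, which widens the spread within its groups. Chance is thus an unlikely source of that count but is not excluded, and the libraries are taken as independent.

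SA187 roots held more OTUs than control roots. OTUs of only 1 to 4 counts in a library made up most of the difference but do not account for all of it. Those of at least 5 counts numbered 116.0 ± 10.4 against 88.7 ± 6.81 (SD, n = 3 each), a ratio of 1.31 with no overlap. Sequencing errors or stray reads that reached 5 counts were not tested for. Depth taken up by dominant OTUs in control roots does not account for all of it either. With the 10 most abundant root OTUs removed and libraries brought to 4108 counts, SA187 roots held 209.6 ± 15.1 OTUs. Control roots then held 164.2 ± 18.5 (SD, n = 3 each), a ratio of 1.28 with no overlap. The full counts were 250.3 and 181.0, so dominance may still account for a part of the difference. Inoculation, the seed coating itself, plot position and differences in sequencing before the subsampling remain open, and none of them was tested. Any condition marked by the letters F and S in the names also remains open. With 3 libraries against 3 the difference may also lie within chance, as the exact permutation p of 0.1 is the smallest possible.

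Soil held fewer OTUs than roots, which an OTU taking most of the soil depth might produce. With Otu001 removed and all 9 libraries brought to 9776 counts, soil richness was 0.645 of root richness, but soil library A with 121 OTUs then lay above the lowest control library. The effect of that dominance therefore cannot be told apart from a poorer soil community with 3 soil libraries. The Chao1 estimate, which extrapolates to unseen OTUs, was 127 ± 36.4 in soil, 0.495 of that in roots with no overlap. It uses the same deposited counts, of which only 9776 to 21156 per soil library lay outside Otu001. It therefore cannot decide whether the subsample was too shallow for rare soil OTUs. A mix-up of samples, a reagent sequence, a bloom of 1 bacterium and the way soil was sampled stay open and were not tested. Any condition marked by the letters F and S in the names was not tested either.

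Most root reads, 94.7 ± 2.89% (SD, n = 6), belonged to OTUs also seen in soil. Soil carried along with the roots is not a likely source of these reads: Otu001, the leading soil OTU, had 6 counts in the 6 root libraries, which puts carry-over at no more than 0.00932% of root reads (upper limit of the exact 95% interval). That bound covers counting error only and holds only if carried soil had the Otu001 share of the libraries labelled soil. Root material in the soil libraries, and recruitment of root bacteria from soil, remain open and were not tested.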
